A study of Rattus norvegicus with 16 samples.

How the data were processed

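RNA from the left ventricle of 16 female rats of about 7 months was measured on Affymetrix RAE 230 2.0 arrays, 1 array per rat. The rats came from generation 16 of 2 lines bred from the N:NIH stock for high or low treadmill running capacity, tested at about 11 weeks of age, and are called High Capacity Runners (HCR) and Low Capacity Runners (LCR). Within each line 4 rats stayed sedentary and 4 followed aerobic interval training on a treadmill. Groups and rat numbers were taken from the sample titles, so the replicates are separate animals.

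The deposited values are log expression values made by the authors with RMA, per the series' design text and the submitters' processing notes, which name RMA and limma without versions. That method corrects the background of the perfect-match probes, quantile-normalizes the arrays and summarises each probe set with a linear model. The base of the logarithm is not given in the sources used here, and the deposited values were taken as log2 because they run from 3.24 to 14.54, as RMA on that scale gives. If the base were another, the differences below would keep their sign and test but not their size in fold. Quantile normalization acts on probes, so the distributions of the summarised values can still differ between arrays. Array medians lay between 5.85 and 5.95. The table held 31099 probe sets, of which 57 Affymetrix controls were left out, and 31042 were tested with no filter on low signal. A difference of log2 values is a compressed measure of the change in RNA, most of all near background, where the level of a probe set also depends on its sequence. Levels of different genes were not compared with each other. The mean level of a probe set served only to choose or rank the probe sets of a gene and as a filter. The number of arrays, 4 per group, limits the precision.

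Gene names came from the array annotation table supplied for the platform. Of the tested probe sets, 20826 had 1 gene symbol, 436 had several and 9780 were not listed there and stay unnamed. Gene IDs of 20758 probe sets with 1 symbol were found in the RefSeq gene table, and 0 symbols needed an update. No genome build or coordinates were used here. The named probe sets stand for 14217 genes.

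Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 16 arrays, with 1 mean per group, 12 residual degrees of freedom and no covariate. The 7 comparisons were the line difference (HCR minus LCR) in sedentary and in trained rats, the training difference (trained minus sedentary) in each line, the difference between the lines in the training response, and both differences averaged over the other factor. All tests were two-sided. P-values were adjusted with the Benjamini-Hochberg method over the 31042 probe sets within a comparison, and a probe set was called at an adjusted p of 0.05 or less. Values after ± are standard errors of the fitted difference unless marked SD, and every adjusted p of a gene is from this limma fit.

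Before the data were examined, 31 lists of pathway genes and 13 lists of cell type markers of the ventricle and its surroundings were fixed from textbook knowledge. They were tested with camera at its preset correlation of 0.01, on the probe set of highest mean for each gene, and adjusted over the 44 lists of a comparison. Camera asks whether a list's genes differ more than the other genes. Its version with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way, and compares them with no other genes. With an estimated correlation no list was called in any of the 7 comparisons.

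The genes named in the text followed a rule fixed at the same time. It took up to 12 genes per direction with the largest change among called genes, in the 4 comparisons of 2 groups only those whose arrays did not overlap between the groups. Where fewer than 3 genes were called, it took the 3 genes of lowest p in each direction, which are said not to pass. It added up to 4 called members of each list that was called or had 3 called members (the 2 of largest change where none was called), and 21 preset genes of contraction, metabolism and matrix. The text names only part of the list members and preset genes, and that part was picked after their values were seen. A gene was represented by its brightest called probe set, or else its brightest one, and other probe sets of a called gene are reported where they differ in sign.

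The fit was tested on simulated values for the sedentary line difference over the 31042 probe sets, drawn with the residual spread of each probe set. Errors were drawn independently, without correlation between genes or shifts of whole arrays, so the rates may not hold on these arrays. Genes of fatty acid oxidation were also shifted as a list and count neither as changes nor as unchanged. The fit recovered 92% of 100 changes of 1.5-fold and 98% of 100 changes of 2-fold, and 14 of the 206 calls, 6.80%, were of unchanged probe sets.

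Values between 2 groups of 4 arrays, such as array medians and marker scores, were compared with exact two-sided permutation tests, whose smallest possible p is 0.0286. A list's score on an array is the mean, over its genes, of the deviation from each gene's mean over the 16 arrays. Correlations of log2 differences were taken across the 14217 genes, which are not independent replicates. They were set beside 1000 simulations of unchanged groups with the residual deviations of whole arrays.

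Alternatives were centring the arrays on their medians, quantile normalization of the summarised values, only probe sets with a mean at or above the median, eBayes with a trend and robust variances, only the arrays compared, array weights, 1 probe set per gene, the rat number as a replicate block, and leaving out each array in turn. For the lists, the mean of all probe sets of a gene was also tried. The arrays left out together, 4 that stood apart on the second principal component and a pair with unusual marker levels, were chosen after seeing the data. No columns of other samples were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.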

Results

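Gene expression was measured in the left ventricle of female rats of 2 lines selected for high (HCR) or low (LCR) running capacity. In each line 4 rats were sedentary and 4 ran on an inclined treadmill for 8 weeks, 5 days per week and 1.5 hours per session, alternating 8 minutes at 85 to 90% of maximal oxygen uptake with 2 minutes at 50 to 60%. The 16 arrays correlated with each other at r between 0.984 and 0.995 across probe sets, with a median r of 0.992 within groups and 0.991 between groups. The first principal component held 24.4% of the variance and the second 16.7%. The spread of values within an array, as the interquartile range of log2 values, was narrower in HCR sedentary rats (2.02 ± 0.057, SD, n = 4) than in LCR sedentary rats (2.17 ± 0.026, SD, n = 4; two-sided exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.286 over 20 tests of array properties). On the first component HCR sedentary arrays lay from -25.6 to -8.77 and LCR sedentary arrays from 4.46 to 14.7. The array of narrowest interquartile range (HCR sedentary rat 5, 1.97) lay lowest on it. That of widest (LCR trained rat 4, 2.27) lay highest, at 23.9. In sedentary rats the range of values and the line cannot be told apart along this component. Xist, the RNA that silences 1 X chromosome in female cells, read between 3.76 and 4.94 on its 4 probe sets in HCR sedentary rat 5 and between 7.56 and 10.34 in the other 15 rats.

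**Figure D1:**
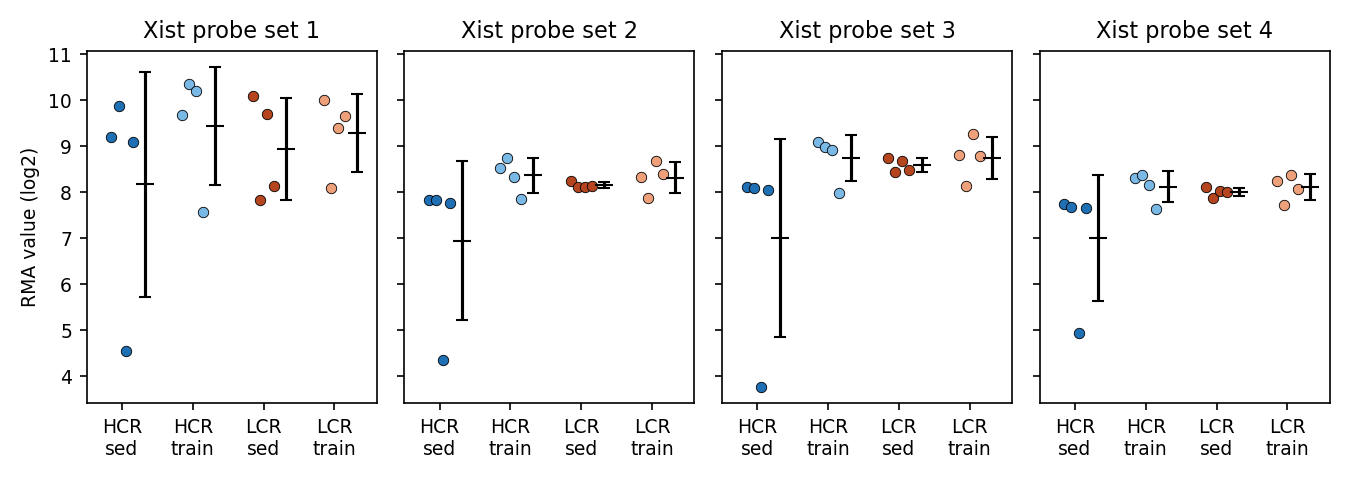
RMA values (log2, y axis) of the 4 probe sets of Xist in the 4 groups (x axis), 1 point per rat, with bars for the group mean ± SD. HCR sedentary rat 5 lies lowest on each of the 4 probe sets, between 3.76 and 4.94.

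The line difference in sedentary rats asked which genes separate the ventricles of the selected lines without training. Retsat, which encodes the enzyme that saturates all-trans-retinol, and Baalc were higher in HCR. Clec3b, which encodes the plasminogen-binding protein tetranectin, was lower in HCR, as were Map1a, a microtubule-associated protein, and Amd1, the S-adenosylmethionine decarboxylase of polyamine synthesis. Pfkfb2, the heart's regulator of glycolysis through fructose bisphosphate, and Ddit4, an inhibitor of mTORC1, were also lower. The ubiquitin ligase gene Trim63 (MuRF1) and its transcription factor Foxo3 were lower, the 2 genes that passed in a list of proteasome genes and atrogenes of which 21 of 23 were lower. Camera called this list, and the call did not hold with another correlation (adjusted p = 0.640 with an estimated correlation).

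Among the named genes Retsat had the largest rise, 4.30-fold (log2 difference 2.11 ± 0.35, 4 rats per group, adjusted p = 0.0134), from a mean of 9.47 ± 0.62 (SD) in LCR to 11.58 ± 0.08 (SD) in HCR. Baalc was 2.16-fold higher (1.11 ± 0.16, adjusted p = 0.00896). Smaller rises were measured for Chrna1, the alpha subunit of the muscle acetylcholine receptor (0.57 ± 0.09, adjusted p = 0.0134), and for Igf2 (0.56 ± 0.11, adjusted p = 0.0221), whose 3 other, dimmer probe sets differed by 0.02 to 0.12 and were not called. Clec3b differed by -1.49 ± 0.26 (adjusted p = 0.0139), and its second probe set by -0.79 (adjusted p = 0.00896). Map1a differed by -1.22 ± 0.19 (adjusted p = 0.00974) and Amd1 by -1.05 ± 0.17 (adjusted p = 0.0128). Klc1, a light chain of the motor protein kinesin, differed by -1.16 ± 0.18 (adjusted p = 0.00994), while a brighter probe set of it differed by -0.29 (adjusted p = 0.0715) and the others by 0.01 and -0.16. Pfkfb2 differed by -0.97 ± 0.13 (adjusted p = 0.00577) on 1 of its 4 probe sets, and the others by 0.15, -0.16 and 0.16 without a call. Ddit4 differed by -0.85 ± 0.16 (adjusted p = 0.0201). Other called genes with large changes were Nt5dc1, Rims1, Myo5b, Ppm1l, Lhfpl2, Ighl2 and Fndc4, higher by 0.57 to 0.89, and Nap1l5, Sphkap, LOC102554789, Dpy19l4 and Akr1b10, with differences from -1.28 to -0.91. Of Akr1b10 a second probe set differed by 0.04, and a dimmer probe set of Nt5dc1 by 0.10. Probe sets disagreed in sign for Lysmd4 (-1.56, adjusted p = 0.0426), whose 3 other probe sets were positive (0.20 to 0.98, not called), and for Ifnar2 (0.68, adjusted p = 0.0400), whose brighter probe set differed by -0.22 (not called). Quantile normalization of the summarised values ended the calls of Nt5dc1, Myo5b, Nap1l5, Sphkap and Lysmd4. The call of Ppm1l was kept in 10 of 26 other settings and left-out arrays.

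Among the gene groups, 21 of the 23 measured genes of the proteasome and atrogenes were lower in sedentary HCR (median -0.15, camera adjusted p = 0.00583, adjusted p = 0.640 with an estimated correlation). Of them Trim63 (-0.56 ± 0.11, adjusted p = 0.0233) and Foxo3 (-0.32 ± 0.09, adjusted p = 0.0484) fell and 21 did not pass, while 6 were lower when adjusted over the list alone. The mitochondrial ribosome was lower in 22 of 25 genes (median -0.13, camera adjusted p = 0.00997, adjusted p = 0.572 with an estimated correlation). Mrps28 (-0.29 ± 0.06, adjusted p = 0.0255) and Mrps22 (-0.23 ± 0.06, adjusted p = 0.0399) fell, and 7 genes were lower when adjusted over the list alone. After quantile normalization of the summarised values the medians of these lists were -0.047 and -0.021, and the calls of Mrps22, Mrps28 and Foxo3 ended. Adipocyte markers were higher in 11 of 13 genes (median 0.14, camera adjusted p = 0.0379, adjusted p = 0.495 with an estimated correlation). Limma called 0 of them, also when adjusted over the list alone. Markers of neurons and Schwann cells were higher in 11 of 14 genes (median 0.13, camera adjusted p = 0.0379, adjusted p = 0.640 with an estimated correlation). Chl1, a neural adhesion molecule, rose (0.37 ± 0.06, adjusted p = 0.0139), also when adjusted over the list alone. The medians of the adipocyte list and of this list were 0.10 and 0.060 after that quantile normalization, and 0.085 and 0.074 with the arrays centred on their medians. Dimmer probe sets of Foxo3 (0.08 and 0.17), Mrps22 (0.28) and Ppm1l (-0.11) went the other way without a call. Marker scores of 5 cell types separated the sedentary groups. In HCR and LCR, fibroblast markers averaged -0.088 and 0.097, cardiomyocyte markers -0.041 and 0.0016, and endothelial markers 0.039 and -0.033. Adipocyte markers averaged 0.040 and -0.079, and markers of neurons and Schwann cells 0.071 and -0.046 (two-sided exact permutation p = 0.0286 for each of the 5, adjusted 0.212 over 52 tests of marker scores).

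Ion channel genes went both ways, with Kcnj3 (0.42 ± 0.09, adjusted p = 0.0256) and Kcnd2 (0.29 ± 0.08, adjusted p = 0.0477) higher and Kcnj11, a pore subunit of the ATP-sensitive potassium channel (-0.26 ± 0.06, adjusted p = 0.0323), lower. Car9, a carbonic anhydrase induced by hypoxia (0.41 ± 0.09, adjusted p = 0.0261), Ndrg1 (0.34 ± 0.08, adjusted p = 0.0350), Nrg1, a ligand of ErbB receptors (0.30 ± 0.07, adjusted p = 0.0356), and Pik3r1, the regulatory subunit of phosphoinositide kinase (0.86 ± 0.23, adjusted p = 0.0462), were higher. None of these 3 lists (channels, angiogenesis and hypoxia, growth signalling) was called by camera. Quantile normalization of the summarised values ended the calls of Kcnd2, Kcnj11, Nrg1 and Pik3r1 (adjusted p from 0.059 to 0.176). It kept those of Kcnj3, Car9 and Ndrg1. The call of Kcnd2 was kept in 7 of 26 other settings and left-out arrays. The growth signalling list had 3 called genes, all higher, and 3 higher and 5 lower when adjusted over the list alone. Its median (-0.089) and its test pointed down. For the angiogenesis and hypoxia list the test pointed up against a median of -0.010. The 21 preset genes of contraction, metabolism and matrix gave 0 calls. Of these, the natriuretic peptide gene Nppa differed by 0.65 ± 0.31 (adjusted p = 0.182), Pdk4, the kinase that inhibits pyruvate dehydrogenase, by 0.74 ± 0.30 (adjusted p = 0.127), and the angiogenic factor Vegfa by -0.25 ± 0.08 (adjusted p = 0.0621). The citrate synthase gene Cs (0.03 ± 0.06) and the myosin gene Myh6 (-0.01 ± 0.07) changed sign between scalings.

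In all, 1549 of 31042 probe sets were called, 623 higher and 926 lower in HCR, with a median absolute log2 difference of 0.32. They stood for 366 genes higher and 680 lower, with 473 probe sets that had no single gene symbol, and 23 reached 2-fold, 6 higher and 17 lower. At an unadjusted p under 0.05 there were 8612, where 1552.1 would be expected by chance. Centring the arrays on their medians gave 298 higher and 2162 lower (12.1% higher against 40.2%), and quantile normalization of the summarised values gave 224 higher and 319 lower. Leaving out 1 array gave 103 without HCR sedentary rat 4, 112 without rat 5 and 491 without rat 6 of that group, and 325, 333 and 35 without LCR sedentary rats 3, 5 and 6. Without that last rat Retsat was not called, and 7 in place of 4 lists were called without LCR sedentary rat 3. With only probe sets with a mean at or above the median 6 lists were called, 5 higher and 1 lower against 2 and 2. The mitochondrial ribosome was no longer called, and the list of neurons and Schwann cells had under 5 genes left and was not tested.

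**Figure D2:**
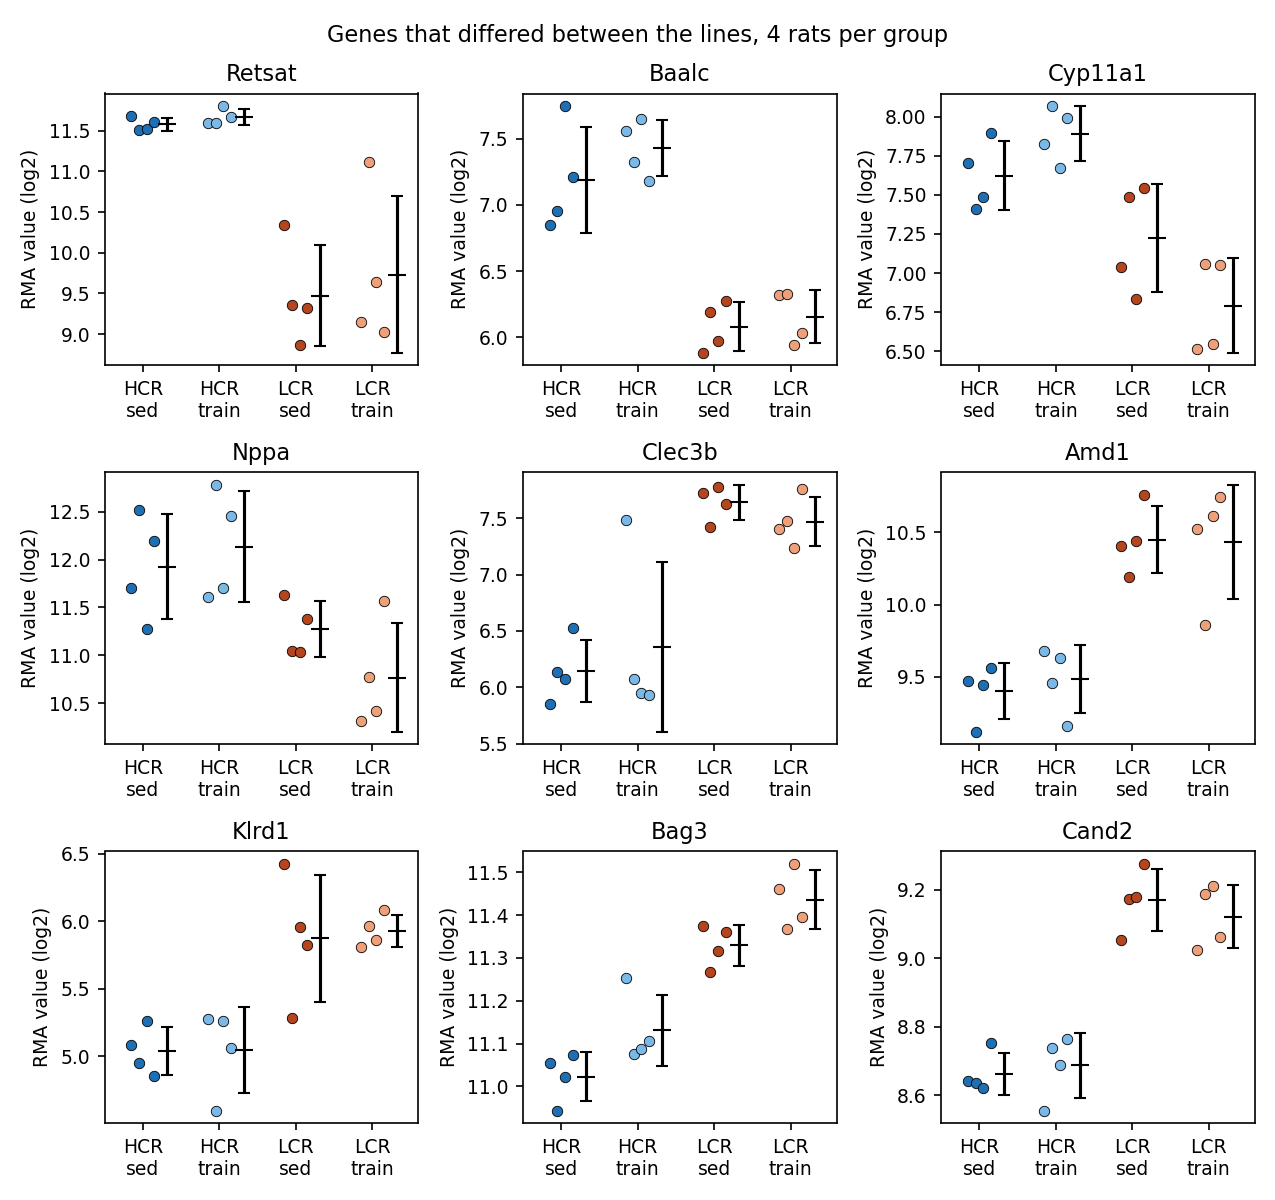
RMA values (log2, y axis) of 9 genes in the 4 groups (x axis), 1 point per rat, with bars for the group mean ± SD. Retsat, Baalc, Cyp11a1 and Nppa had higher means in both HCR groups than in both LCR groups, and Clec3b, Amd1, Klrd1, Bag3 and Cand2 lower means.

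The same line difference was then taken between trained rats. Retsat and Baalc were again higher in HCR, and so was Cyp11a1, which cleaves the side chain of cholesterol in the first step of steroid synthesis. Lower in HCR were RT1-Ba, an alpha chain of MHC class II, Amd1, Sqor, which oxidises sulfide in mitochondria, and Bag3, a co-chaperone of heat shock proteins in muscle. As lists by camera, genes of protein folding, the proteasome, the interferon response and antigen presentation were lower in trained HCR. None of these list calls held with another correlation (lowest adjusted p = 0.582 with an estimated correlation).

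Retsat was 3.82-fold higher (1.93 ± 0.35, 4 rats per group, adjusted p = 0.0481), Baalc 2.41-fold (1.27 ± 0.16, adjusted p = 0.00326) and Cyp11a1 2.14-fold (1.10 ± 0.17, adjusted p = 0.0149). Bean1 was higher by 0.71 ± 0.07 (adjusted p = 0.000232). Vps52, part of a complex that tethers vesicles to the Golgi, was higher on a pair of probe sets (0.54 ± 0.09, adjusted p = 0.0376, and 0.65, adjusted p = 0.000232). Acot2, a mitochondrial acyl-CoA thioesterase, was higher by 0.51 ± 0.09 (adjusted p = 0.0471), while its brighter probe sets differed by -0.09 and 0.21 and were not called. RT1-Ba differed by -1.88 ± 0.32 (adjusted p = 0.0376) and on a second probe set by -2.13 (adjusted p = 0.0437), but by 0.15 and 1.12 on the others, which were not called. Sqor differed by -0.92 ± 0.15 (adjusted p = 0.0278), Amd1 by -0.95 ± 0.17 (adjusted p = 0.0460) and Cand2 by -0.43 ± 0.06 (adjusted p = 0.0126). Coq9, of coenzyme Q synthesis, differed by -0.75 ± 0.10 (adjusted p = 0.00316) on its dimmer probe set and by -0.07 on the bright one (not called). The remaining called genes were Dcps (0.36), Akr1b10 (-1.19, with 0.06 on its other probe set), Dpy19l4 (-1.15), Crebl2 (-0.79, with 0.06 on a brighter probe set) and Bag3 (-0.31 ± 0.06, adjusted p = 0.0481).

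The proteasome and atrogenes were lower in 21 of 23 genes (median -0.16, camera adjusted p = 3.31e-07, adjusted p = 0.696 with an estimated correlation). None of them was called, and Psma4 was at -0.28 ± 0.12 (adjusted p = 0.651). Of the list 3 were lower when adjusted over the list alone. Heat shock and protein folding genes were lower in 20 of 23 (median -0.11, camera adjusted p = 0.00137, adjusted p = 0.582 with an estimated correlation), and Bag3 fell, also when adjusted over the list alone. The interferon response was lower in 19 of 23 genes (median -0.15, camera adjusted p = 0.00137, adjusted p = 0.796 with an estimated correlation). None of it was called, and Psmb8, a subunit of the immunoproteasome, was at -0.78 ± 0.23 (adjusted p = 0.394). In this list 5 genes were lower when adjusted over the list alone. Its scores in LCR trained rats 1 to 4 were -0.014, -0.37, 0.24 and 0.63, and rat 4 was also the highest of the 16 rats for antigen presentation (0.42) and macrophage markers (0.42). Antigen presentation genes were lower in 14 of 19 and lymphocyte markers in 12 of 16 (camera adjusted p = 0.0471 for each, adjusted p = 0.796 with an estimated correlation). RT1-Ba fell, and adjusted over the list alone the antigen presentation list had 1 gene higher and 5 lower and the lymphocyte list 1 higher and 2 lower. Klrd1, a receptor chain of natural killer cells, was at -0.88 ± 0.19 (adjusted p = 0.110) and the chemokine Ccl5 at -1.23 ± 0.34 (adjusted p = 0.295). Cytosolic ribosome genes were lower in 20 of 24 (median -0.072, camera adjusted p = 0.0189, adjusted p = 0.796 with an estimated correlation). Limma called 0 of them, also when adjusted over the list alone. Preset genes gave 0 calls, with Nppa at 1.37 ± 0.31 (adjusted p = 0.156) and the actin gene Acta1 at 0.72 ± 0.29 (adjusted p = 0.585).

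Between trained lines 30 probe sets were called by limma, 14 higher and 16 lower, standing for 7 genes higher and 9 lower, and 13 reached 2-fold. At an unadjusted p under 0.05 there were 2274. The count was 16 without HCR sedentary rat 4 or 5, 13 without rat 6, 14 without HCR trained rat 4 or 5 and 17 without rat 6. It was 12 without LCR trained rat 1 or 3, and 53 without rat 2. With only probe sets with a mean at or above the median the calls of the antigen presentation and lymphocyte lists ended. With 1 probe set per gene 11 were called, and calls of Retsat, Dcps, Bag3, Amd1, Akr1b10 and Acot2 were kept in 8 or fewer of up to 26 other settings and left-out arrays.

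Of the 30 probe sets called between trained lines, 20 were also called between sedentary lines, all in the same direction, where 0.758 would be expected for independent lists. The lists are not fully independent, since both comparisons use the same standard error of a probe set, which can raise the overlap by itself. Of the 1549 called in sedentary rats, 82.4% had the same sign in trained rats, with a median ratio of trained to sedentary differences of 0.239. Choosing probe sets by 1 of the comparisons lowers such a ratio by itself, so it does not measure a loss of the line difference with training. For the 30 chosen in trained rats the median ratio of sedentary to trained differences was 0.595. Across 14217 genes, which are not independent replicates, the line differences in sedentary and trained rats correlated with r = 0.434 and rho = 0.394, while 95% of simulations with unchanged groups lay between -0.435 and 0.433. Without LCR trained rat 4 this r was 0.284. The training differences of the lines correlated with r = 0.0433 and rho = -0.0045, and without LCR trained rat 3 or 4 r was -0.0195 or -0.0833.

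**Figure D3:**
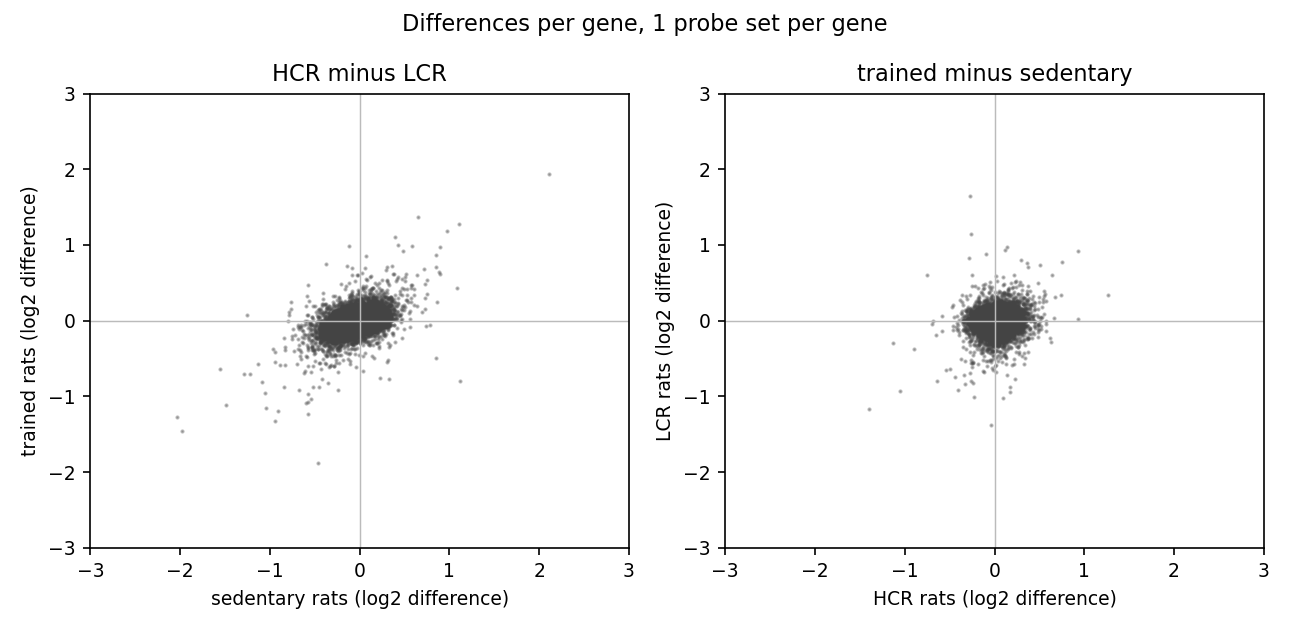
Log2 differences per gene, 1 point per gene and 1 probe set per gene: HCR minus LCR in sedentary (x axis) against trained rats (y axis), and trained minus sedentary in HCR (x axis) against LCR rats (y axis). The axes run from -3 to 3 and leave out 1 gene, Fam111a, and r is 0.434 for the line differences and 0.0433 for the training differences.

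Averaged over training, the line difference was the mean of those in sedentary and trained rats, and it compared 8 rats with 8. Retsat, Baalc and Cyp11a1 were higher in HCR, together with Nppa, the gene of atrial natriuretic peptide, Nfe2l1, a transcription factor of proteasome genes, Abca1, a transporter of cholesterol, and Uqcc6, an assembly factor of respiratory complex III. Lower were Clec3b, Amd1, Map1a, the MHC genes RT1-CE10 and RT1-Ba, Klrd1 and Ccl5. The calls of RT1-CE10 and Ccl5 ended under quantile normalization of the summarised values. Pfkfb2 and Hk2, both of glycolysis, were lower as well. As lists by camera, genes of the proteasome, of protein folding and of the mitochondrial ribosome were lower, and these calls did not hold with another correlation (adjusted p = 0.480 with an estimated correlation for each).

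Retsat was 4.06-fold higher (2.02 ± 0.25, 8 rats per line, adjusted p = 0.000822), Baalc 2.28-fold (1.19 ± 0.12, adjusted p = 0.000124), Nfe2l1 2.11-fold (1.08 ± 0.21, adjusted p = 0.0127) and Nppa 2.02-fold (1.01 ± 0.22, adjusted p = 0.0217). Nppa was the 1 called gene among the 21 preset genes, and Nppb, of brain natriuretic peptide, was at 0.36 ± 0.13 (adjusted p = 0.112). The other probe sets of Nfe2l1 differed by 0.43 and 0.18 and were not called. Abca1 was higher by 1.02 ± 0.22 (adjusted p = 0.0220) on 1 probe set, with -0.19 on a brighter one and 0.43 (adjusted p = 0.0522) and 0.01 on dimmer ones. Uqcc6 was higher by 0.93 ± 0.18 (adjusted p = 0.0128), Cyp11a1 by 0.75 ± 0.12 (adjusted p = 0.00514) and Fgf12, an intracellular modulator of sodium channels, by 0.78 ± 0.14 (adjusted p = 0.00953), with 0.81 (adjusted p = 0.0131) and 0.09 on its other probe sets. RT1-CE10 differed by -1.72 ± 0.42 (adjusted p = 0.0357), Clec3b by -1.30 ± 0.18 (adjusted p = 0.00195), Amd1 fell by 1.00 ± 0.12 (adjusted p = 0.000806) and Klrd1 by -0.86 ± 0.13 (adjusted p = 0.00426). RT1-Ba differed by -1.17 ± 0.23 (adjusted p = 0.0132), on a second probe set by -1.36 (adjusted p = 0.0138), and by 0.37 and 0.43 on the others, which were not called. Ccl5 differed by -0.91 ± 0.24 (adjusted p = 0.0470). The next changes in size were those of Nt5dc1, Ano5, Pla2g12a and Cwc25, higher by 0.70 to 0.75, and of Lysmd4, Dpy19l4, Akr1b10, Nap1l5, Map1a and LOC102554789, with differences from -1.10 to -0.95. The other probe sets of Lysmd4 (0.17, 0.16 and 0.77) and Akr1b10 (0.05) differed in sign and were not called.

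The proteasome and atrogenes were lower in 21 of 23 genes (median -0.18, camera adjusted p = 5.53e-06, adjusted p = 0.480 with an estimated correlation). Of these 5 fell, among them Psmb3 (-0.22 ± 0.05, adjusted p = 0.0222), Psmb4 (-0.21 ± 0.05, adjusted p = 0.0266) and Trim63 (-0.31 ± 0.08, adjusted p = 0.0432), and 16 were lower when adjusted over the list alone. Quantile normalization of the summarised values ended these 3 calls and that of Psma1, and gave a list median of -0.11. Heat shock and protein folding genes were lower in 19 of 23 (median -0.11, camera adjusted p = 0.0145, adjusted p = 0.480 with an estimated correlation). Bag3 (-0.31 ± 0.04, adjusted p = 0.00103) and the heat shock transcription factor gene Hsf1 (-0.22 ± 0.06, adjusted p = 0.0423) fell, and 5 were lower when adjusted over the list alone. The call of Hsf1 ended under the same normalization, which gave a list median of -0.041. The mitochondrial ribosome was lower in 20 of 25 genes (median -0.065, camera adjusted p = 0.0240, adjusted p = 0.480 with an estimated correlation). Mrpl15 and Mrps28 fell by 0.20 each, and 8 genes were lower when adjusted over the list alone. The median was -0.0034 under that normalization. In glycolysis, Pfkfb2 (-0.67 ± 0.09, adjusted p = 0.00183), the hexokinase gene Hk2 (-0.34 ± 0.07, adjusted p = 0.0228) and Ugp2 (-0.30 ± 0.07, adjusted p = 0.0372) fell. The 3 other probe sets of Pfkfb2 differed by 0.05, -0.22 and 0.02 and were not called. Of 25 genes 3 were lower and 1 higher when adjusted over the list alone. In the extracellular matrix, Sparc (0.25 ± 0.06, adjusted p = 0.0233) and the protease inhibitors Timp3 (0.24 ± 0.06, adjusted p = 0.0312) and Timp4 (0.28 ± 0.07, adjusted p = 0.0449) rose, 3 of 34 genes also when adjusted over the list alone. In lymphocyte markers, Klrd1 and Ccl5 fell and Cd79b, of the B cell receptor, rose (0.22 ± 0.05, adjusted p = 0.0222), 1 gene higher and 2 lower when adjusted over the list alone. Antigen presentation had Ciita, the transactivator of MHC class II genes, higher (0.24 ± 0.05, adjusted p = 0.0183) and RT1-Ba and RT1-S3 (-0.65 ± 0.17, adjusted p = 0.0470) lower, with 1 gene higher and 5 lower when adjusted over the list alone. Other probe sets of Ciita (-0.07) and RT1-S3 (0.10) went the other way without a call, and a further pair of RT1-S3 was called at -0.63 and -0.70. Camera called none of these last 4 lists. For the extracellular matrix the test and mean (0.011) pointed up against a median of -0.0054.

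Over both states 1191 probe sets were called, 450 higher and 741 lower, for 267 genes higher and 544 lower, and 26 reached 2-fold. Centring the arrays gave 283 higher and 1496 lower (15.9% higher against 37.8%), and quantile normalization of the summarised values gave 723. The count was 520 and 529 without HCR sedentary rats 4 and 5, 674 and 607 without HCR trained rats 5 and 6, 610 and 532 without LCR sedentary rats 5 and 6, and 2575, 581 and 567 without LCR trained rats 2, 3 and 4. The called lists numbered 5 without HCR trained rat 6 or LCR trained rat 2, 6 without LCR sedentary rat 3 and 1 without LCR trained rat 1, against 3 with all arrays. With only probe sets with a mean at or above the median 2 lists were called higher and 1 lower, against 0 and 3. The calls of the mitochondrial ribosome and of heat shock and protein folding ended there. Among single genes, calls of Ccl5, RT1-S3, Lysmd4, Ano5, Timp4 and Psma1 were kept in 7 to 9 of 25 other settings and left-out arrays. Those of Hsf1, Pla2g12a, Trim63, RT1-CE10 and Ugp2 were kept in 10 to 13, and those of Retsat, Baalc, Clec3b and Amd1 in all 25.

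**Figure D4:**
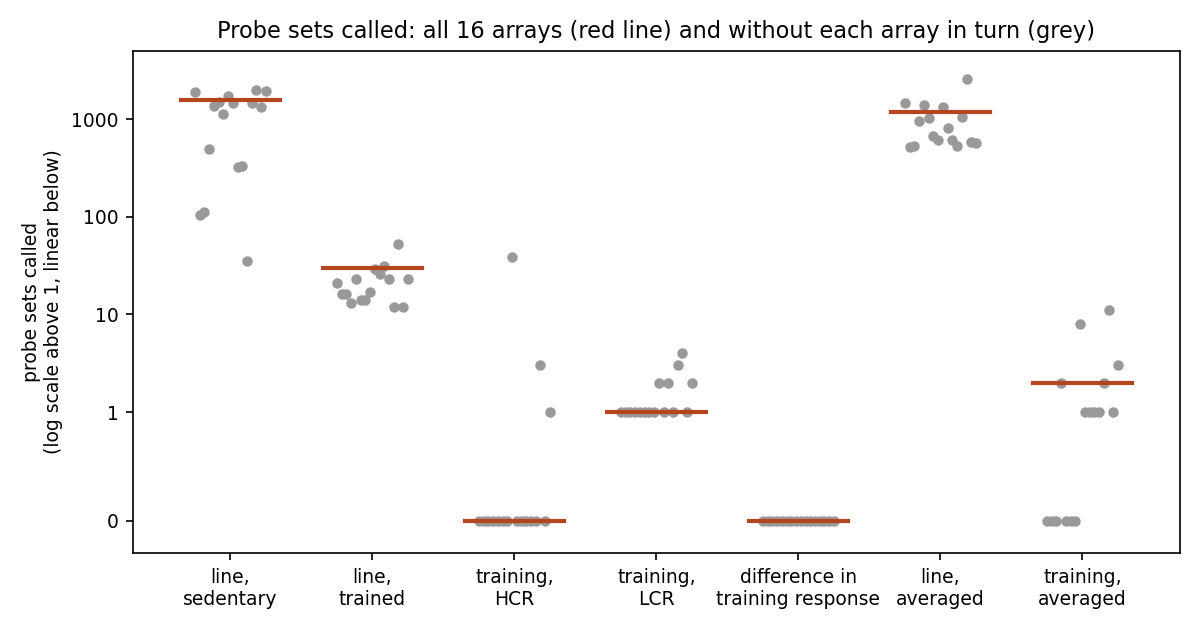
Probe sets called (y axis, logarithmic above 1 and linear below) in the 7 comparisons (x axis), with all 16 arrays as a red line and without each array in turn as grey points. The sedentary line difference ran from 35 to 1994 around 1549, and the trained one from 12 to 53 around 30.

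The training difference in HCR asked what 8 weeks of interval training changed in rats of high inborn capacity. No single gene passed the test. As groups, genes of the mitochondrial ribosome and of glycolysis were higher after training by camera, and immediate early genes, the transcription factors that respond first to a stimulus, were lower. None of these 3 list calls held with another correlation (lowest adjusted p = 0.436 with an estimated correlation).

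The mitochondrial ribosome was higher in 24 of 25 genes (median 0.10, camera adjusted p = 7.98e-05, adjusted p = 0.436 with an estimated correlation). Limma called 0 of these genes, also when adjusted over the list alone, and their median was 0.037 after quantile normalization of the summarised values. Array properties moved with it, the interquartile range being 2.02 in sedentary and 2.13 in trained HCR (two-sided exact permutation p = 0.0571). Scores of cardiomyocyte markers averaged -0.041 in sedentary and 0.012 in trained HCR (two-sided exact permutation p = 0.0286, adjusted 0.212 over 52 tests). Glycolysis genes were higher in 21 of 25 (median 0.056, camera adjusted p = 0.0193, adjusted p = 0.672 with an estimated correlation), with 2 higher when adjusted over the list alone. The muscle enolase gene Eno3 was at 0.74 ± 0.18 (adjusted p = 0.184) and Pfkfb2 at 0.52 ± 0.13 (adjusted p = 0.189), with -0.11, 0.05 and -0.19 on its other probe sets. Immediate early genes were lower in 22 of 23 (median -0.25, camera adjusted p = 1.42e-05, adjusted p = 0.600 with an estimated correlation). None was called, also when adjusted over the list alone. HCR sedentary rat 3 scored -0.085 for this list, against 0.23 to 0.29 in the others of its group. HCR trained rats 3 to 6 scored 0.068, -0.077, -0.31 and -0.25. Fos was at -1.40 ± 0.60 (adjusted p = 0.327), with -0.12 on a dimmer probe set, and Egr1 at -1.06 ± 0.39 (adjusted p = 0.278). The SD of Fos was 0.97 in sedentary and 1.08 in trained HCR. The lowest p-values, none of which passed, were those of Actr3b (0.57 ± 0.09, adjusted p = 0.0927), Ppm1j, a protein phosphatase (0.55 ± 0.09, adjusted p = 0.0935), Nars2, a mitochondrial asparaginyl-tRNA synthetase (0.66 ± 0.11, adjusted p = 0.0935), Igf2 (-0.58 ± 0.11, adjusted p = 0.109), Cdca7l and Kcnmb1. Preset genes gave 0 calls, with Vegfa at 0.27 ± 0.08 (adjusted p = 0.210) and the glucose transporter gene Slc2a4 at 0.24 ± 0.09 (adjusted p = 0.275). Ppargc1a, a coactivator of mitochondrial biogenesis, was at 0.04 ± 0.11, and its sign changed under quantile normalization.

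With limma 0 probe sets were called, and 4308 had an unadjusted p under 0.05, where 1552.1 would be expected by chance. Without HCR trained rat 6 the count was 39, without LCR trained rat 2 it was 3 and without LCR trained rat 4 it was 1, and array weights gave 27. Without the 4 arrays that stood apart on the second principal component, a set chosen after seeing the data, it was 111, 98 higher and 13 lower. The glycolysis list was not called with only probe sets with a mean at or above the median, where 1 list was called higher and 3 lower, against 2 and 1.

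The training difference in LCR asked the same of rats of low inborn capacity. Genes of fatty acid oxidation and targets of PPAR, the nuclear receptors that switch the heart to fat as fuel, were higher after training as groups. Markers of macrophages, adipocytes and smooth muscle and genes of inflammation were also higher, and immediate early genes, calcium handling genes and genes of apoptosis and the cell cycle lower. These are list calls by camera, and none held with another correlation (lowest adjusted p = 0.263 with an estimated correlation). No named gene passed the test, and 1 unnamed probe set rose.

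PPAR targets and fuel switch genes were higher in 13 of 14 (median 0.21, camera adjusted p = 9.02e-06, adjusted p = 0.263 with an estimated correlation), 3 of them when adjusted over the list alone. The rats of the groups overlapped. Scores of this list were 0.031, 0.15, 0.39 and -0.10 in LCR trained rats 1 to 4. In LCR sedentary rats 2, 3, 5 and 6 they were -0.30, 0.032, -0.18 and -0.062. Pdk4 was at 0.93 ± 0.30 (adjusted p = 0.629), the fatty acid transporter gene Slc27a1 at 0.34 ± 0.09 (adjusted p = 0.539) and Ucp3 at 0.45 ± 0.18 (adjusted p = 0.819). Fatty acid oxidation was higher in 22 of 26 genes (median 0.060, camera adjusted p = 0.00154, adjusted p = 0.853 with an estimated correlation). Limma called 0 of them, also when adjusted over the list alone. Scores of this list also overlapped, at 5.2e-05, 0.12, 0.12 and -0.12 in the trained rats and -0.22, 0.070, -0.091 and 0.0034 in the sedentary ones, in the same order. Macrophage and myeloid markers were higher in 16 of 17 (median 0.15, camera adjusted p = 0.00154, adjusted p = 0.680 with an estimated correlation). Their scores in LCR trained rats 1 to 4 were -0.012, -0.077, 0.11 and 0.42, and the group means of -0.032 in sedentary and 0.11 in trained LCR had a two-sided exact permutation p = 0.400. Inflammation and acute phase genes were higher in 17 of 24 (median 0.054, camera adjusted p = 0.0208, adjusted p = 0.263 with an estimated correlation). The macrophage and inflammation lists had 0 genes called when adjusted over the list alone. Adipocyte markers were higher in 11 of 13 (median 0.043, camera adjusted p = 0.00406, adjusted p = 0.263 with an estimated correlation), 2 of them when adjusted over the list alone. The lipase gene Pnpla2 was at 0.47 ± 0.13 (adjusted p = 0.479). Their score was -0.079 in sedentary and 0.021 in trained LCR (two-sided exact permutation p = 0.0286, adjusted 0.212 over 52 tests). Smooth muscle and pericyte markers were higher in 10 of 15 (camera adjusted p = 0.0468, adjusted p = 0.371 with an estimated correlation), 1 when adjusted over the list alone. Immediate early genes were lower in 18 of 23 (median -0.18, camera adjusted p = 0.00154, adjusted p = 0.626 with an estimated correlation), 0 when adjusted over the list alone. Fos was at -1.17 ± 0.60 (adjusted p = 0.904), with 0.08 on a dimmer probe set. Calcium handling genes were lower in 12 of 19 (camera adjusted p = 0.0348, adjusted p = 0.455 with an estimated correlation), 2 when adjusted over the list alone. Apoptosis and cell cycle genes were lower in 15 of 22 (camera adjusted p = 0.0468, adjusted p = 0.497 with an estimated correlation), 3 when adjusted over the list alone. Mcm2, a subunit of the replicative helicase, was at -0.51 ± 0.09 (adjusted p = 0.351). The lowest p-values among named genes, which did not pass, were those of Nrep (-0.53 ± 0.08, adjusted p = 0.123), Igfbp5, an IGF-binding protein (-0.80 ± 0.13, adjusted p = 0.133), Dctpp1, Obp3, Mtfp1 and Orm1.

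The called probe set, 1374916_at, rose by 1.00 ± 0.10 (adjusted p = 0.000831), from a mean of 5.89 in sedentary LCR to 6.89 in trained LCR, next to 6.77 and 6.85 in sedentary and trained HCR. A fit of only the arrays compared called 0 probe sets. The probe set falls outside the rule for named genes and was singled out after its values were seen. At an unadjusted p under 0.05 there were 1728. The count was 2 without LCR sedentary rat 2 or 5 or LCR trained rat 4, 3 without LCR trained rat 1 and 4 without LCR trained rat 2, and 4 in place of 9 lists were called without LCR trained rat 1 or 3. The lists of calcium handling, inflammation and smooth muscle lost their calls with only probe sets with a mean at or above the median.

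Whether the lines differed in their training response was tested as the training difference in HCR minus that in LCR. PPAR targets, inflammation genes and markers of adipocytes and lymphocytes moved less upward or more downward in HCR than in LCR, and the mitochondrial ribosome more upward in HCR, as lists by camera. None of these calls held with another correlation (lowest adjusted p = 0.192 with an estimated correlation), and no single gene passed. PPAR targets were lower in 12 of 14 genes (median -0.15, camera adjusted p = 0.0193, adjusted p = 0.771 with an estimated correlation), with Pdk4 at -0.82 ± 0.42 (adjusted p = 0.539). Inflammation genes were lower in 21 of 24 (median -0.090, camera adjusted p = 0.0170, adjusted p = 0.192 with an estimated correlation), with the chemokine gene Ccl2 at -0.67 ± 0.23 (adjusted p = 0.475). Adipocyte markers were lower in 11 of 13 (median -0.10, camera adjusted p = 0.0193, adjusted p = 0.218 with an estimated correlation) and lymphocyte markers in 13 of 16 (median -0.12, camera adjusted p = 0.0321, adjusted p = 0.771 with an estimated correlation). The mitochondrial ribosome was higher in 23 of 25 (median 0.093, camera adjusted p = 0.0352, adjusted p = 0.771 with an estimated correlation), and its median was -0.0012 after quantile normalization of the summarised values. Its scores were -0.139 to -0.065 in the HCR sedentary rats and -0.024 to 0.065 in all others. Its calls between sedentary lines, for training in HCR and here share those HCR sedentary arrays and are not separate results. The calls of adipocyte markers share the LCR sedentary arrays in the same way. In these 5 lists 0 genes were called when adjusted over the list alone. The lowest p-values were those of Paqr6 (0.70 ± 0.13), Mmaa, of cobalamin metabolism (0.56 ± 0.11), and Camk2d, the main cardiac calmodulin-dependent kinase (0.40 ± 0.08), each with an adjusted p of 0.368, and of Dmbt1, LOC102549347 and Krt14. With limma 0 probe sets were called, and 3068 had an unadjusted p under 0.05. The 5 called lists became 2 without HCR sedentary rat 3, 3 without HCR sedentary rat 4, HCR trained rat 3 or 4 or LCR trained rat 4, 9 without LCR trained rat 2 and 0 without LCR trained rat 3. With only probe sets with a mean at or above the median 7 were called, all lower, and the call of the mitochondrial ribosome ended.

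Training in LCR was also set against the line difference, to see whether it moved genes toward their level in sedentary HCR. Across 14217 genes the training difference in LCR and the sedentary line difference correlated with r = 0.362 and rho = 0.357, and without LCR trained rat 2 r was 0.195. Both share the sedentary LCR rats, and simulations of unchanged groups gave a mean r of 0.486, from 0.108 to 0.760 in 95% of them. The covariance was 0.00788 against a simulated mean of 0.00613, a difference of 0.00175. With the sedentary LCR rats divided between the comparisons in 6 ways, r averaged 0.0757, from -0.0688 to 0.240.

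Averaged over the lines, Ppm1j was higher in trained rats, a call that most left-out arrays ended, and immediate early genes were lower in all 23 measured members. Genes of fatty acid oxidation, mitochondrial translation, complex I, mitochondrial biogenesis, glycolysis and the proteasome were higher as groups, and atrial and cell cycle genes lower. These groups were called by camera, and none held with another correlation (lowest adjusted p = 0.234 with an estimated correlation). Ppm1j rose by 0.47 ± 0.07 (8 rats per state, adjusted p = 0.0421), from 7.59 to 8.15 in HCR and from 7.78 to 8.17 in LCR. Its call was kept in 10 of 25 other settings and left-out arrays, and in 4 of the 16 fits with 1 array left out. The second call was the unnamed probe set 1374916_at (0.54 ± 0.07, adjusted p = 0.0308).

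Immediate early genes had a median of -0.18 (camera adjusted p = 1.72e-08, adjusted p = 0.234 with an estimated correlation), and 4 were lower when adjusted over the list alone. Fos was at -1.28 ± 0.42 (adjusted p = 0.404), with -0.02 on a dimmer probe set, and Egr1 at -0.99 ± 0.28 (adjusted p = 0.320). The mitochondrial ribosome was higher in 22 of 25 genes (median 0.073, camera adjusted p = 0.000219, adjusted p = 0.234 with an estimated correlation). Fatty acid oxidation was higher in 22 of 26 (median 0.041, camera adjusted p = 0.000766, adjusted p = 0.753 with an estimated correlation). These lists had 0 and 2 genes higher when adjusted over the list alone, and medians of 0.042 and 0.026 after quantile normalization of the summarised values. PPAR targets were higher in 11 of 14 (median 0.12, camera adjusted p = 0.00672, adjusted p = 0.574 with an estimated correlation). Glycolysis genes were higher in 21 of 25 (median 0.023, camera adjusted p = 0.0137, adjusted p = 0.586 with an estimated correlation), with Eno3 at 0.54 ± 0.12 (adjusted p = 0.236). In each of these 1 gene was higher when adjusted over the list alone. Mitochondrial biogenesis genes were higher in 16 of 20 (camera adjusted p = 0.0137, adjusted p = 0.498 with an estimated correlation). Complex I subunits were higher in 27 of 31 and the proteasome and atrogenes in 23 of 23 (camera adjusted p = 0.0365 for each, adjusted p = 0.807 with an estimated correlation). Of these last 3 lists 0 genes were called when adjusted over the list alone. Macrophage markers were higher in 14 of 17 (median 0.14, camera adjusted p = 0.0137, adjusted p = 0.753 with an estimated correlation), 0 when adjusted over the list alone. Atrial and conduction markers were lower in 10 of 12 (median -0.14, camera adjusted p = 0.0137, adjusted p = 0.234 with an estimated correlation), with the atrial myosin light chain gene Myl4 at -0.66 ± 0.23 (adjusted p = 0.425). Apoptosis and cell cycle genes were lower in 18 of 22 (median -0.053, camera adjusted p = 0.0174, adjusted p = 0.498 with an estimated correlation). Adjusted over the list alone these had 1 and 3 genes lower. Named genes of low p that did not pass were Tmem116, Csdc2, Igfbp5, Nrep and Colgalt2, each with an adjusted p of 0.116.

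Averaged over the lines 2 probe sets were called by limma and 2867 had an unadjusted p under 0.05. The count was 0 without any 1 of HCR sedentary rats 3, 4 and 5 or HCR trained rats 3, 4 and 5, and 1 without any of the 4 LCR sedentary rats or LCR trained rat 3. It was 8 without HCR trained rat 6 and 11 without LCR trained rat 2, and 7 in place of 11 lists were called without HCR sedentary rat 4. With only probe sets with a mean at or above the median 6 were called, 3 higher and 3 lower against 8 and 3. The calls that ended were those of complex I, mitochondrial biogenesis, glycolysis, the proteasome and macrophage markers.

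**Figure D5:**
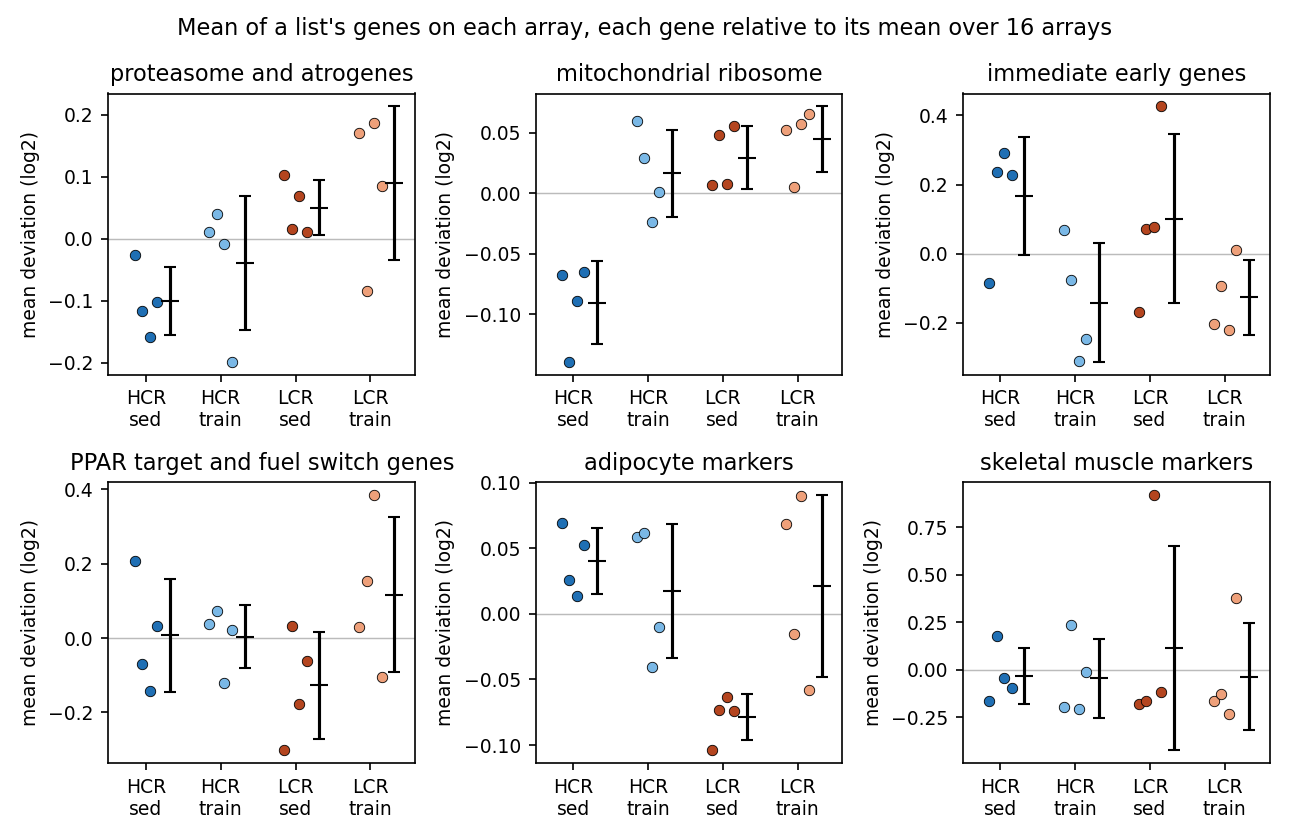
Scores of 6 gene lists (y axis, log2, the mean over the list's genes of the deviation from each gene's mean over 16 arrays) in the 4 groups (x axis), 1 point per rat, with bars for the group mean ± SD. LCR sedentary rat 5 stands apart for skeletal muscle markers at 0.92.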

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

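The tests on Xist were chosen only after its values were seen, and the other tests in this part were planned.

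In HCR sedentary rat 5 the 4 probe sets of Xist read 4.54, 4.36, 3.76 and 4.94, far below the other 3 rats of its group and the other 15 rats (7.56 or more). A failed array is argued against, but not excluded, by its mean correlation of 0.993 with the other arrays of its group. That lies within the range of the other arrays, as does its 3′ minus 5′ difference of Gapdh. The difference of Actb was the highest of the 16 (1.26, next 1.25), which the rule for this test counts toward a failed array. The array also had the narrowest interquartile range (1.97), the highest median (5.95) and the lowest value on the first principal component (-25.6) of the 16. A male rat is argued against because no probe set of that array exceeded the highest of the other 15 by 1 log2 unit or more (the largest excess was 0.906). Probe sets of the Y-linked genes Tspy1 and Sry and 1 of Uty were within the others' range, Eif2s3y read 3.53 against 3.50 or less, and a second Uty probe set read lower (6.15 against 6.92 or more), although no male array shows how high they would read. A single X chromosome in that rat is a candidate explanation: X-linked genes that escape inactivation in rodents deviated there by a median of -0.445, against -0.0698 or more on the others, with Eif2s3 at 8.71 (others 9.26 or more), Ddx3x at 10.71 (10.95 or more) and Kdm5c within range, and a sample from another animal was not tested.

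Single rats stood apart from the other 3 of their group in 32 of the 588 groups of 4 values examined for genes and in 11 of 176 for gene lists. With 6 among the 16 groups of Xist values and 0 among 16 of array properties that made 49 of 796, where chance alone gives about 1 in 20 groups, or 39.8. The values of these rats follow, in log2, with the range of the other 3 in parentheses.
In HCR sedentary rat 3, Klc1 read 8.11 (7.27 to 7.40), Angptl4 read 6.50 (5.22 to 5.34), Cd14 read 6.77 (6.61 to 6.64) and Cidec read 5.07 (5.29 to 5.31). In HCR sedentary rat 4, Crebl2 read 6.10 (6.26 to 6.28). In HCR sedentary rat 6, Acot2 read 7.23 (7.10 to 7.11) and Cand2 read 8.75 (8.62 to 8.64). In HCR trained rat 3, Clec3b read 7.49 (5.93 to 6.07) and Bag3 read 11.25 (11.08 to 11.11). In HCR trained rat 5, Sqor read 7.96 (7.78 to 7.80) and Gzmb read 7.05 (5.31 to 5.56). In HCR trained rat 6, Igf2 read 8.08 (7.67 to 7.69), Klc1 read 7.20 (7.55 to 7.57), Ddit4 read 6.90 (7.65 to 7.68), Kcnj3 read 7.71 (7.29 to 7.35) and the third Xist probe set read 7.99 (8.91 to 9.09). In LCR sedentary rat 2, Nppb read 12.09 (11.52 to 11.56), Mrpl20 read 9.94 (9.68 to 9.72), C1qb read 8.65 (8.17 to 8.21), Mrps35 read 9.67 (9.38 to 9.41), Timp3 read 10.09 (10.28 to 10.29), Ucp2 read 10.71 (11.44 to 11.55) and the second Xist probe set read 8.25 (8.12 to 8.14). In LCR sedentary rat 3, Nt5dc1 read 4.28 (4.99 to 5.08). In LCR sedentary rat 5, Ano5 read 9.76 (8.90 to 9.02) and Pla2g12a read 8.65 (7.66 to 7.72). In LCR sedentary rat 6, Atp2a2 read 14.03 (13.96 to 13.97). In LCR trained rat 1, Nt5dc1 read 5.96 (5.12 to 5.25), Atp2a2 read 14.02 (13.98 to 13.99) and Cdkn1a read 10.14 (10.43 to 10.48). In LCR trained rat 2, Timp3 read 9.99 (10.33 to 10.38). In LCR trained rat 3, Pln read 13.73 (13.70 to 13.70) and Angptl4 read 8.30 (5.30 to 5.42). In LCR trained rat 4, RT1-Ba read 10.88 (9.91 to 9.94).

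Scores of gene lists that stood apart were these. In HCR sedentary rat 3, autophagy scored -0.0085 (-0.10 to -0.084) and immediate early genes scored -0.085 (0.23 to 0.29). In HCR sedentary rat 4, TCA cycle scored -0.085 (0.011 to 0.026) and ATP synthase subunits scored -0.060 (-0.0045 to 0.0051). In HCR trained rat 4, complex I subunits scored -0.046 (0.019 to 0.032) and ATP synthase subunits scored -0.085 (-0.0035 to 0.013). In HCR trained rat 5, interferon response scored 0.11 (-0.23 to -0.17). In LCR sedentary rat 2, sarcomere scored 0.073 (-0.0040 to 0.0042). In LCR sedentary rat 5, skeletal muscle markers scored 0.92 (-0.18 to -0.12). In LCR trained rat 2, endothelial markers scored -0.12 (0.012 to 0.026). In LCR trained rat 4, apoptosis and cell cycle scored 0.020 (-0.072 to -0.060).

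The lines differed in the training response of 5 gene lists by camera with its preset correlation. Its adjusted p was 0.0193 for PPAR targets and fuel switch genes and 0.0193 for adipocyte markers. For inflammation and acute phase genes it was 0.0170, for lymphocyte markers 0.0321 and for the mitochondrial ribosome 0.0352. None of these held with an estimated correlation (adjusted p = 0.192 or more).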

How the results depend on the processing

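The arrays left out together were chosen after seeing the data, and all other settings before. Of 881 values of named, called genes under other settings 665 kept direction and call and 216 lost the call, and of 1504 with 1 array left out 1058 kept it and 446 lost it. Of the named genes that were not called, 19 of 1193 and 11 of 2000 such values passed. No call changed direction. Signal over background and 4 arrays per group limit what can be called, and the causes of the changes below were not tested except where a setting uses fewer probe sets or arrays.

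Between sedentary lines 1549 probe sets became 2460 with arrays centred on their medians (1224 of them shared), 543 with quantile normalization again (476 shared) and 4183 with array weights. Quantile normalization gave 723 for the line difference averaged over training and 5 for the averaged training difference. Array weights gave 27 for training in HCR. A fit of only the arrays compared called 2 for training in HCR and 0 in LCR. With 1 probe set per gene the count was 11 between trained lines, 0 for training in LCR and 1 for averaged training. Without the 4 arrays apart on the second principal component (HCR trained 6, LCR sedentary 3 and 6, LCR trained 2) the counts were 109 between sedentary lines (66 shared), 111 for training in HCR, 2 in LCR, 1 for the difference in training response, 629 for the averaged line difference and 49 for averaged training. Without HCR sedentary 5 and LCR sedentary 5 together, low in Xist and high in skeletal muscle markers, they were 16 between sedentary lines (15 shared), 3 for training in LCR, 285 for the averaged line difference and 0 for averaged training. The cause was not tested.

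Gene lists called by camera fell to 0 in each of the 7 comparisons with an estimated correlation. By fry 9 were called between sedentary lines, 0 between trained lines, 1 for training in HCR, 0 in LCR, 0 for the difference in response, 6 for the averaged line difference and 0 for averaged training. Without the 4 arrays apart on the second principal component the lists called were 10 between sedentary lines, 15 for training in LCR and 7 for the averaged line difference. The mean of all probe sets of a gene gave 3 lists for the difference in response, and probe sets with a mean at or above the median gave 6 for averaged training. The same setting gave 5 lists higher and 1 lower between sedentary lines (2 and 2 before, 2 shared), and 2 higher and 1 lower for the averaged line difference (0 and 3 before, 1 shared). The cause was not tested.

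With the rat number as a replicate block 3000 probe sets were called between sedentary lines, 8 for training in HCR, 0 in LCR and 0 for averaged training, and 3 lists were called between trained lines and 3 for the difference in response. The sample titles do not say whether a shared number links rats of different groups, and the deviations leave it open. Of 16 same-number pairs in different groups, 6 deviated together with r over 0.1. The median r of the 16 was 0.035 (from -0.231 to 0.339), against a median of -0.0064 for other numbers.

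Leaving out 1 array at a time, the counts of probe sets ranged from 35 to 1994 between sedentary lines, 12 to 53 between trained lines, 0 to 39 for training in HCR, 1 to 4 in LCR, 0 to 0 for the difference in response, 520 to 2575 for the averaged line difference and 0 to 11 for averaged training. In the same order the lists called ranged from 3 to 7, 4 to 6, 2 to 4, 4 to 12, 0 to 9, 1 to 6 and 7 to 12. The correlation across genes ranged from 0.284 to 0.483 for the line differences, from -0.0833 to 0.160 for the training differences and from 0.195 to 0.473 for training in LCR against the line difference.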

Other observations

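The tests of the spread within trained against sedentary groups, of the smallest p that the test of 2 states could give, of the states among sedentary rats, and of other probe sets without the RT1-Ba pair were chosen only after results were seen. The others were planned. A few transcripts were present at high level in some rats and near background in the rest. Fam111a, a protease gene of the nucleus, averaged 11.42 in 7 rats, 5 HCR and 2 LCR, and 4.84 in the other rats, with a gap of 6.14 log2 units between the states. The MHC gene RT1-T24-4 was high in 12 rats, all 8 LCR and 4 HCR (8.85 against 5.75), and Pxmp4, of the peroxisomal membrane, in 4 rats (7.98 against 5.52). In all, 6 probe sets had a gap of 2 or more with at least 3 rats on each side, and 3 of them were unnamed. These genes fall outside the rule for named genes and were singled out after their values were seen.

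A hypothesis is that these states are inherited. Training as the whole cause of the states is argued against, since both states occurred among the 8 sedentary rats in all 6 probe sets. With 4 or 12 rats high, as for Pxmp4 and RT1-T24-4, two-sided Fisher's exact p cannot be below 0.0769, so a response to training cannot be told apart for these 2. The high state of Pxmp4 occurred in 2 trained and 2 sedentary rats, and that of RT1-T24-4 in 6 and 6. Among the 4 other probe sets the states followed training in 0 and the line in 3, all unnamed (two-sided Fisher's exact p = 0.0014, 0.00699 and 0.00699, not adjusted). This pools the lines and leaves a response to training open: in these 3 the rats that departed from the line's state, 1 HCR, 2 LCR and 2 LCR, were all trained. Inherited variants may give such states, with genotypes not given in the sources used here.

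Far more probe sets differed between the lines in sedentary (1549) than in trained rats (30). A larger spread between trained rats could not lower the trained count through the standard error. The counts come from 1 fit in which the 4 groups share 1 estimate of the spread. Each probe set thus has the same standard error in both comparisons. The differences themselves were smaller, with an SD over all probe sets of 0.184 between sedentary and 0.134 between trained lines. In the 1549 probe sets the SD within trained groups was a median of 1.11 times that within sedentary groups (1.03 to 1.14 with 1 array left out). Fits of the compared arrays alone gave 2061 and 20, which decides nothing, since a larger spread between trained rats lowers the count of such a fit. With the sedentary differences put on the trained arrays such a fit called 117. The test set for a larger spread was undecided, since the ratio stayed above 1 while the 117 stayed well above the 20. The narrower range of values on the HCR sedentary arrays is consistent with part of the gap: quantile normalization again left 543 between sedentary lines, still above the 29 between trained lines. A difference between the lines in the response to training stays open, since its own test called 0 probe sets while the spread of trained line differences beyond error was 0.574 of the sedentary one.

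Line differences of 2-fold or more could come from a sequence difference under the probes of 1 probe set in place of a difference in expression. Of the 13 genes with such a difference in the average over training, 7 had other probe sets above the array median, and 33.3% of those 15 comparisons differed in the same direction at an unadjusted p of 0.05. Among the 5 that did, 2 were the pair of RT1-Ba probe sets set against each other, and the others were in Clec3b, Klc1 and Nfe2l1. Without that pair it was 3 of 13, or 23.1%, below the 1 in 4 that was set beforehand for a sequence difference, so the outcome rests on the pair. For Lysmd4, Abca1 and Akr1b10 no other probe set above the array median differed in the same direction (a dimmer one of Abca1 differed by 0.43, adjusted p = 0.0522). Outside its pair, RT1-Ba had probe sets that went the other way, by 0.37 and 0.43, without a call. The genes outside those 7, among them RT1-CE10, Retsat and Baalc, had no other probe set above the array median. Retsat and Baalc have 1 probe set each. For all of these genes, RT1-Ba included, the explanation cannot be told apart from expression, since no probe sequences were used here.

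Chance was assessed by dividing the same arrays in other ways. Between sedentary lines 1 of the 35 splits of the 8 arrays called as many as 1549 probe sets, the real one, and the highest other called 5. Between trained lines 1 of the 35 splits of the 8 arrays called as many as 30, with 1 as the highest other, and for the line difference averaged over training 1 of 100 splits of the 16 arrays called as many as 1191, with 52 as the highest other. Chance is argued against for these counts, but not excluded. With 35 splits no share can be below 2.86%, and the shares were not adjusted over the comparisons. Nor can the splits tell the line from an array property that separates the same groups, as the interquartile range did in sedentary rats. For the training counts chance cannot be excluded. Every split calls at least 0, so the splits decide nothing for the 0 in HCR or the 0 for the difference in response. There 35 of 35 and 100 of 100 splits called as many by necessity, with 6 and 77 as the highest others. As many as the 1 in LCR were called in 11 of 35 splits (highest other 6), and as many as the 2 for averaged training in 6 of 100 (highest other 3). The split with 77 calls may point to a structure of the arrays other than the groups, and what sets it apart was not tested.

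For the counts of gene lists chance cannot be excluded in any comparison. As many as the 4 lists between sedentary lines were called in 27 of 35 splits (highest other 15), the 6 between trained lines in 12 of 35 (highest other 9), the 3 for training in HCR in 24 of 35 (highest other 14) and the 9 in LCR in 9 of 35 (highest other 16). For the difference in response 65 of 100 splits called as many as 5 lists (highest other 14), for the averaged line difference 84 of 100 as many as 3 (highest other 14) and for averaged training 8 of 100 as many as 11 (highest other 14).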
